A study of Mus with 13 samples.

How the data were processed

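Single-cell RNA sequencing (10x Chromium 3' chemistry) covered 13 libraries of cells from tumours grown in the mouse pancreas from KPC1199 cells, a pancreatic ductal adenocarcinoma line. Per the labels, the hosts were mice on normal diet (ND), mice with diet-induced obesity (DIO) or ob/ob mice, which are obese because they lack leptin. Housing was thermoneutral (TN, 30 °C) or sub-thermoneutral (STN, 22 °C). The groups are ND STN, DIO TN and DIO STN with 3 libraries each, and ob/ob TN and ob/ob STN with 2 each. The labels give 2 possible sort gates, live CD45-positive leukocytes or all live cells, without saying which library had which.

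The deposited matrices hold whole UMI counts per gene and cell barcode, made by the authors with Cell Ranger on mm10; Seurat is also named in the submitters' processing notes. Per the file headers, the counts come from Cell Ranger 6.0.0 in library series RS-0376 (replicates 1 and 2 of the ND and DIO groups), from 6.1.2 in RS-0384 (their replicate 3) and from 7.0.0 in RS-0391 (ob/ob). Whether reads in introns were counted is not given in the sources used here, and 7.0.0 counts them by default. Counts of 9 antibody tags, present in the 6 RS-0376 libraries, were kept apart from the 32285 genes and enter no comparison.

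Cells with at least 500 UMIs, at least 200 genes and under 15% mitochondrial UMIs were kept, 106178 of 119835 barcodes. High mitochondrial content removed most in the ob/ob libraries, of which 72.4, 76.2, 79.6 and 81.7% of barcodes were kept, and in DIO STN 3, with 72.7%. Scrublet (in scanpy 1.11.5, Python 3.11.15, expected rate 0.06) marked under 0.5% of cells at its automatic threshold in each of the 13 libraries, so cells with a doublet score over 0.25 were removed, 2108 in all, which left 104070 cells. Counts were scaled per cell, logged and reduced to 2000 variable genes and 30 principal components, and cells were grouped by Leiden clustering (leidenalg 0.10.2, 15 neighbours, resolution 1) into 28 clusters. Mixed clusters were divided again (1000 genes, 20 components, resolution 0.5), which gave 51 in all. Clusters were named from marker genes fixed beforehand. Cells called X-like below belong to a cluster so named; 8 clusters with 2398 cells (2.30%) stayed unnamed and are in no class. No batch correction was applied before clustering.

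UMIs of a class were summed per library, leaving out libraries with under 20 cells of the class. Genes passing filterByExpr were tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, robust quasi-likelihood fit) with a term per group and a term for series RS-0384, over all libraries at once. This left 7 residual degrees of freedom in the immune classes and 2 in the epithelial one. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. For 24 gene lists, camera (limma 3.58.1, log2 CPM with prior count 3) tested whether members moved one way more than other genes did, with a preset correlation of 0.01 and, beside it, one estimated from the data. Its p-values are adjusted over the 24 lists within a class and comparison. Numbers of cells per class were tested with edgeR with the log of the library's immune-named cells as offset, adjusted over 6 immune classes. Exact permutation tests of the shares are two-sided. For single genes of a class, CPM stands for UMIs per 1e6 UMIs of the class sum after TMM scaling. List means per library, marker sums, free RNA, within-cluster and whole-library values use CPM without TMM scaling, so they are on another scale. Log2 changes are fitted values, first group minus second, with the SE that the fit gives. A statement that a list held means that its call stayed under adjusted p 0.05 without each library of the comparison in turn. Where this leaves 1 library in a group, it is assumed to vary like the other groups. In the epithelial class the ND and DIO groups have 1 library each, ND STN 1 and DIO TN 2. The spread there then rests on the other ob/ob pair alone.

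The genes named were fixed by rule: in macrophage-, T- and neutrophil-like cells, up to 5 higher and 5 lower called genes of at least 20 CPM with the largest change, or, where none passed, the 3 genes with the smallest p, as values; up to 4 members of each called list; and 19 preset genes in the class where each is most abundant, some of which are not reported here. Receptor variable segments were left out. Members are named here for lists that held, a narrowing chosen after the data were seen, as was every gene named because another tool or setting called it. Groups, classes, lists, tests, the rule and most alternatives were chosen before the data were examined. Later additions are the fit on RS-0376 alone, leaving out libraries for the gene lists, a crossed pairing in epithelial cells, counting unnamed sub-clusters as dendritic, all counts over other divisions of the libraries, the tests of the dendritic-like share against series and neutrophil numbers, the test of single libraries for the interferon list, free RNA per list member and clusters per library.

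Same-numbered libraries of the ND and DIO groups were checked for shared deviations from their group means. In macrophage-like cells the correlations were 0.504, 0.341 and 0.675 between DIO STN and ND STN, and 0.649, 0.318 and 0.727 between DIO STN and DIO TN. In neutrophil-like cells they were 0.580, 0.236 and 0.727, and 0.718, 0.286 and 0.783. T-like cells gave 0.203, 0.104 and 0.253 against ND STN, and 0.214, 0.0962 and 0.177 against DIO TN, where 1 pair stayed under 0.1. The pairing is thus not given by the labels, and replicate 3 is also the only library of RS-0384 in its group. Differently numbered libraries of RS-0376 correlated at 0.0578 to 0.385 in macrophage-like, −0.103 to 0.577 in neutrophil-like and −0.0125 to 0.147 in T-like cells. The replicate 2 values lay within these ranges and those of replicate 1 above them. Pairing of replicate 2 thus has little support in the data. A fit with a replicate block in place of the series term was run beside each test.

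Alternatives were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no filter on low counts, no series term, a replicate block, only the groups compared, a stricter cell filter (500 genes, 10% mitochondrial UMIs, 99395 cells), doublets kept, cells named one by one (62.6% of cells got the same name), limma on shares, all cells as the denominator of shares, and each library left out in turn.

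The tests were also tested on simulated data of the same sizes. All libraries were drawn from 1 mean per gene, so no series or replicate structure was simulated. Many genes were changed at once, which makes the adjusted threshold easier to reach. The shares of genes called can thus overstate the power in the real data. For a change of 4-fold, edgeR called 80.4, 84.5 and 76.8% of changed genes in macrophage-like cells (DIO STN against DIO TN, DIO STN against ND STN, ob/ob STN against ob/ob TN), 62.4, 73.1 and 71.7% in T-like cells and 56.25, 60.4 and 51.0% in neutrophil-like cells. For a change of 2-fold it called 50.5, 48.5 and 26%, then 5.10, 11.2 and 13%, and 18.75, 15.6 and 5%. With the preset correlation camera called a simulated 1.5-fold list in 7 of 9 tests, and with an estimated one in 0 of 9. Simulated genes varied independently of each other, so these counts do not show how either setting behaves where genes of a list vary together. Fibroblast-like cells, at most 22 in a library, were too few to test, and no cluster was named endothelial.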

Results

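The series holds 13 single-cell RNA libraries of mouse tumours in 5 groups. They set lean against obese hosts, and mild cold (22 °C) against thermoneutral housing (30 °C), at which a mouse spends little energy on keeping warm. ND STN, DIO TN and DIO STN have 3 libraries each, and ob/ob TN and ob/ob STN have 2 each. Gene UMIs (unique molecular identifiers, each a counted RNA molecule) per library were 61141353, 43436574 and 41495075 in ND STN. They were 56077629, 50676166 and 29123869 in DIO TN, and 56650241, 63842343 and 10723539 in DIO STN. The ob/ob TN libraries had 78894598 and 65558707, and the ob/ob STN libraries 80749035 and 86947934. Kept cells per library ranged from 3417 in DIO STN 3 to 10237 in ob/ob STN 2. The median UMIs per kept cell ranged from 1732 in DIO STN 3 to 4380 in ob/ob STN 1. Nothing in the labels says that the libraries come from separate animals, so the p-values measure the spread between these samples, part of which may be technical. Cells are never counted as replicates. The ob/ob libraries are a series of their own, so the model and the series cannot be told apart.

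Neutrophil-like cells, phagocytes that are among the first to enter inflamed tissue, were the largest class in each group. They made up 63.5% ± 7.61 of immune-named cells in ND STN, 86.1% ± 6.60 in DIO TN and 81.1% ± 4.95 in DIO STN (SD, n = 3 each). In ob/ob TN they made up 70.4% ± 1.18 and in ob/ob STN 64.9% ± 3.86 (SD, n = 2 each). Macrophage-like cells, tissue phagocytes with their monocyte precursors, came next on average in all groups. Their shares were 16.3% ± 5.49 in ND STN, 10.2% ± 5.51 in DIO TN, 12.1% ± 7.99 in DIO STN, 22.1% ± 4.24 in ob/ob TN and 26.7% ± 0.758 in ob/ob STN. Epithelial- or tumour-like cells were 9.44% ± 0.601 of all cells in ob/ob TN and 8.75% ± 3.72 in ob/ob STN. They were 0.318% ± 0.340 in ND STN, 0.197% ± 0.0572 in DIO TN and 0.123% ± 0.103 in DIO STN. A CD45 sort gate removes such cells, and which libraries were so sorted is not given in the sources used here. Unnamed clusters held 2.69% ± 0.735 of cells in ND STN, 1.90% ± 1.15 in DIO TN, 2.63% ± 1.06 in DIO STN, 1.68% ± 0.310 in ob/ob TN and 2.79% ± 1.90 in ob/ob STN.

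Within a class the groups filled different clusters. Macrophage-like cells of the ND and DIO groups lay in a cluster led by Mmp12, Lpl, C1qa and Arg1 (54.9 to 68.2% of the class) and in a monocyte-like one led by Ccr2 and Plac8 (31.6 to 45.1%), as group means. Between libraries the first held 27 to 74.4% of the class in RS-0376 and 94.0 to 96.1% in RS-0384. Those of ob/ob TN and ob/ob STN lay mostly (86.5 and 89.5%) in one led by Cacna1d, Pid1, Pf4 and Mertk. B-, T-, NK- and dendritic-like cells too had clusters with 0 cells outside the ob/ob libraries. These libraries are a series of their own, counted with Cell Ranger 7.0.0, so model, series and software cannot be told apart here. Neutrophil-like cells of ob/ob TN lay in a pair of clusters (49.5 and 44.2%). There ob/ob STN had 32.0 and 25.5% of its cells. A further 32.2% of them, from 6.07 to 58.4% between its libraries, lay in another cluster. In DIO STN the leading neutrophil cluster held 28.8% of the class on average and 61.6% in one library.

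**Figure D1:**
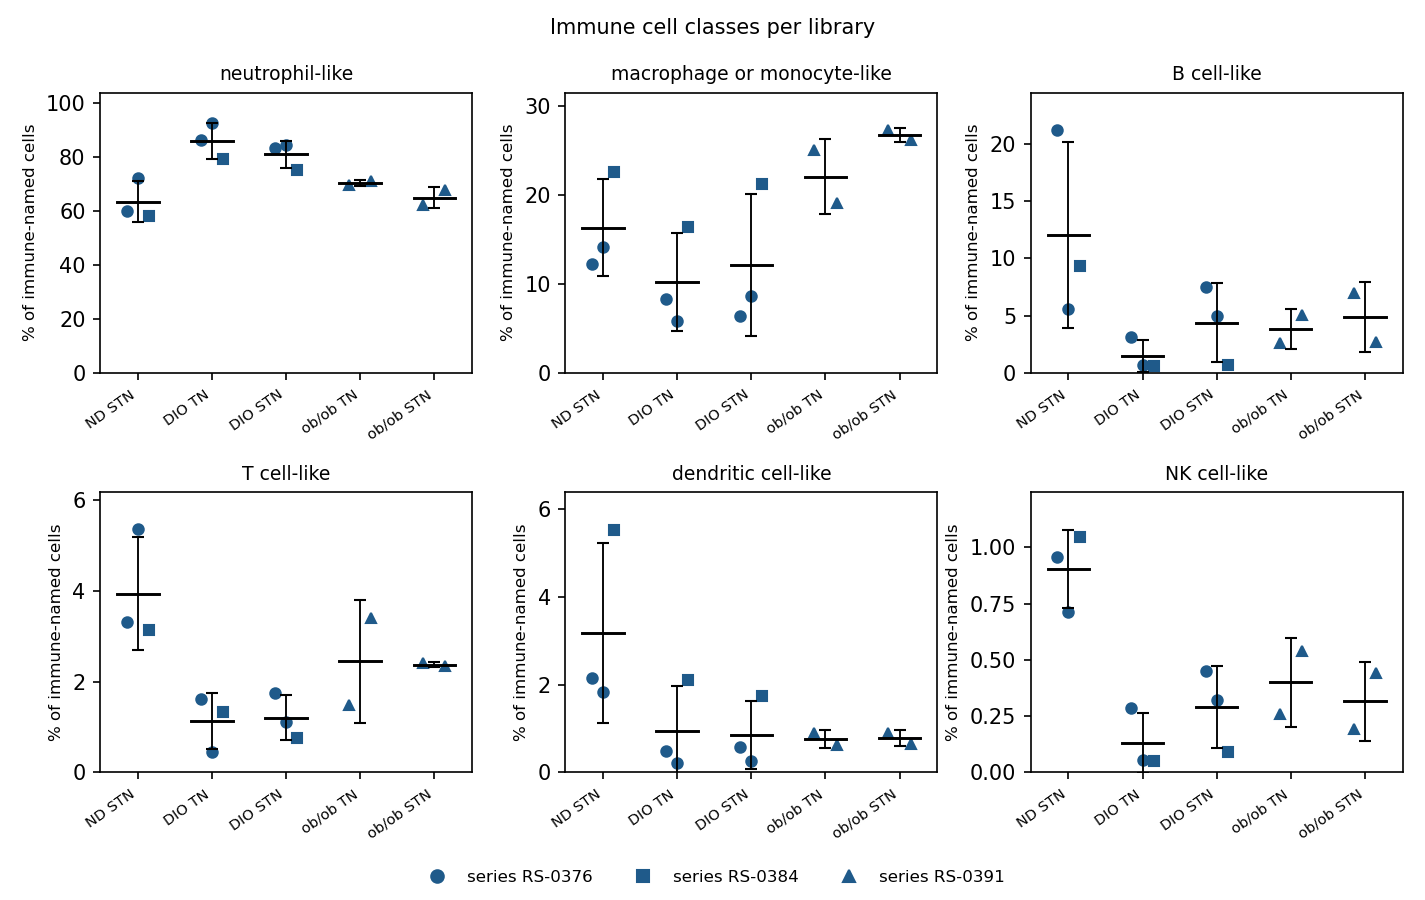
Share of 6 immune classes in each library, in percent of immune-named cells (y axes start at 0), by group; points are libraries with the marker giving the library series, and the black line and bars are mean ± SD. Dendritic-, T- and NK-like shares of all 3 DIO STN libraries lie below those of all 3 ND STN libraries, and their neutrophil-like shares lie above.

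The comparison of DIO STN with DIO TN asks how housing at 22 °C against 30 °C shapes the tumour infiltrate in diet-induced obesity. In neutrophil-like cells, 22 of 23 measured genes of the type I interferon response, antiviral genes switched on by interferon alpha and beta, had lower fitted values in DIO STN. The list was lower as a whole (median log2 −0.83, camera adjusted p = 4.53e-10). This call had adjusted p = 0.703 with an estimated correlation. Rsad2, which makes a nucleotide that blocks viral RNA synthesis, averaged 81.0 ± 65.4 CPM in DIO STN and 367 ± 342 in DIO TN (SD, n = 3 each; log2 −2.13, SE 0.806). Ifit2, which binds viral RNA, was at 5.26 ± 4.45 and 17.8 ± 17.1 CPM (log2 −1.65, SE 0.590). The mean log2(CPM + 1) over the list was 3.50, 4.99 and 4.18 in DIO STN 1, 2 and 3 and 4.71, 6.22 and 4.64 in DIO TN 1, 2 and 3. A neutrophil-like cluster led by Rsad2 and Ifit1 held 0.831, 5.50 and 2.30% of the class in DIO STN 1, 2 and 3 and 6.44, 15.7 and 2.24% in DIO TN 1, 2 and 3. Whether the list differs through this mix of clusters or within cells was not tested in the DIO groups. All 21 measured genes of the lipid-associated macrophage list, which holds lysosomal and lipid-handling genes, had lower fitted values too (median log2 −0.73, camera adjusted p = 6.71e-08). It had adjusted p = 0.703 with an estimated correlation. For this macrophage list, neither free RNA of macrophages nor the mix of neutrophil clusters was tested.

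Gpnmb, a glycoprotein of phagosomes and lysosomes on that list, was at 5.54 ± 1.20 CPM in DIO STN and 18.1 ± 6.13 in DIO TN (SD, n = 3 each). Lipa, the lysosomal acid lipase, was at 47.7 ± 17.3 and 75.7 ± 47.2 CPM, and the lysosome membrane protein Cd63 at 349 ± 65.9 and 482 ± 61.8. The T cell effector list was lower in neutrophil-like cells (10 of 13 measured genes, median log2 −0.90, camera adjusted p = 0.00512). For this list, adjusted p = 0.703 with an estimated correlation. Its smallest p there belonged to Ccl5, a chemokine made by T and NK cells (0.684 ± 0.404 and 2.75 ± 1.71 CPM). The next members are not specific to T cells. Ccl3 (1060.5 ± 229 and 2447 ± 1483 CPM) and Ccl4 (452 ± 241 and 1259 ± 857) are chemokines that activated neutrophils also make. Zeb2 (164 ± 71.4 and 313 ± 178) is a transcription factor of myeloid cells as well. The T cell effector call was lost in series RS-0376 alone (adjusted p = 0.0577). There the interferon list (adjusted p = 4.99e-06) and the lipid-associated list (adjusted p = 4.40e-05) kept their calls.

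Genes of oxidative phosphorylation were higher in neutrophil-like cells of DIO STN (23 of 25, median log2 0.20, camera adjusted p = 0.000759). This list had adjusted p = 0.703 with an estimated correlation. Cox7c, a subunit of the last enzyme of the respiratory chain, was at 437 ± 86.4 CPM in DIO STN and 348 ± 94.6 in DIO TN (SD, n = 3 each). In macrophage-like cells all 26 ribosomal protein genes had higher fitted values (median log2 0.14, camera adjusted p = 5.92e-06). They had adjusted p = 0.876 with an estimated correlation. Among them Rps24 was at 4733 ± 455 CPM in DIO STN and 4116 ± 917 in DIO TN. In RS-0376 alone the adjusted p was 0.0163 for oxidative phosphorylation and 0.0172 for ribosomal proteins. RS-0384 has 1 library per group, which gives no test there. No gene of the lists that held passed the test, adjusted over the list alone or over all genes.

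No single gene was called by edgeR in macrophage-, T- or neutrophil-like cells, with 329 of 13009, 278 of 8827 and 478 of 14154 genes at an unadjusted p under 0.05. DESeq2 called 0, 2 and 0. Without the filter on low counts edgeR called 113, 5 and 151, and other divisions of the 6 libraries gave up to 606, 28 and 710.0. The DESeq2 genes, named after their values were seen, are Tmem176a and Tmem176b, membrane proteins abundant in type 17 lymphocytes. In T-like cells Tmem176a was at 55.1 ± 51.9 CPM in DIO STN and 244 ± 138 in DIO TN (SD, n = 3 each; DESeq2 log2 −2.51, adjusted p = 0.0175). Tmem176b was at 44.2 ± 28.5 and 253 ± 147 CPM (DESeq2 log2 −2.57, adjusted p = 0.0312). A T-like cluster led by Il17a and Trdc held 9 of 141, 2 of 41 and 15 of 76 T-like cells in DIO TN 1, 2 and 3. In DIO STN it held 0 of 151, 1 of 104 and 5 of 25, and its part in the difference was not tested. By edgeR, Tmem176a (log2 −2.57, SE 0.524, adjusted p = 0.892) had the smallest p in T-like cells. Furin, a protease that activates precursor proteins (50.3 ± 9.36 and 169 ± 70.9 CPM), and Pbx3, a transcription factor (17.5 ± 1.77 and 0.771 ± 1.34), followed. The T-like sums held 679027, 398233 and 52534 UMIs in DIO STN 1, 2 and 3 and 454172, 226741 and 199229 in DIO TN 1, 2 and 3. Levels such as those of Pbx3 thus rest on few UMIs, most of all in DIO STN 3.

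In neutrophil-like cells the smallest p-values belonged to Pgf, a growth factor of the VEGF family (1.63 ± 1.61 CPM in DIO STN and 0.281 ± 0.234 in DIO TN), Dock10, an activator of small GTPases (30.4 ± 9.13 and 69.3 ± 17.8), and Snai3 (1.55 ± 0.108 and 4.45 ± 1.45). In macrophage-like cells they belonged to the lipid receptor Gpr18 (2.14 ± 0.711 and 0.364 ± 0.10), Gm31718 (8.84 ± 0.870 and 15.6 ± 1.17) and Gm13822 (0.756 ± 0.575 and 5.18 ± 5.09). All 6 had an edgeR adjusted p of 1. No immune class was called in share. The largest differences on the log2 scale were in B-like cells, 4.39% ± 3.45 in DIO STN and 1.49% ± 1.41 in DIO TN (SD, n = 3 each; log2 1.36, SE 0.817, edgeR adjusted p = 0.455; exact permutation p = 0.3). NK-like cells were 0.288% ± 0.182 and 0.131% ± 0.134 (log2 1.14, SE 0.722, edgeR adjusted p = 0.455; exact permutation p = 0.2). With 3 libraries against 3 the smallest two-sided exact p is 0.1. Within series the log2 ratios were 1.71 (RS-0376) and 0.079 (RS-0384) for B-like and 1.19 and 0.79 for NK-like cells.

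As a limit of this comparison, other divisions of the same 6 libraries gave p-values as small for each list that held. The smallest was 1.24e-27 for the interferon list in neutrophil-like cells (unadjusted 1.89e-11 here) and 5.49e-13 for the lipid-associated list (5.59e-09 here). Of the 9 other divisions, 3 part all same-numbered libraries as the real one does, and their smallest p was 0.000438 and 0.00223 for these 2 lists. It was 0.209 for the T cell effector list, 2.80e-05 for oxidative phosphorylation and 3.07e-08 for ribosomal proteins. The interferon mean was lower in DIO STN in each of the 3 same-numbered pairs, and with a replicate block the list had camera adjusted p = 2.99e-13. The pairing of replicate 2 has little support in the data. Summed CPM of neutrophil marker genes in T-like cells, a measure of free RNA, was 7349 ± 4062 in DIO STN and 4348 ± 2256 in DIO TN (SD, n = 3 each).

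The comparison of DIO STN with ND STN asks what diet-induced obesity changes at the same temperature. Dendritic-like cells, which carry tumour antigens to T cells, fell from 3.17% ± 2.04 of immune-named cells in ND STN to 0.861% ± 0.773 in DIO STN (SD, n = 3 each; log2 −2.07, SE 0.420, edgeR adjusted p = 0.00615). Their shares were 1.84 to 5.52% in ND STN and 0.270 to 1.74% in DIO STN. T-like cells fell from 3.94% ± 1.24 to 1.21% ± 0.497 (log2 −1.71, SE 0.535, edgeR adjusted p = 0.0283). NK-like cells, which kill tumour cells without prior priming, fell from 0.904% ± 0.173 to 0.288% ± 0.182 (log2 −1.77, SE 0.694, edgeR adjusted p = 0.0398). Macrophage-like cells fell from 16.3% ± 5.49 to 12.1% ± 7.99 (log2 −0.57, SE 0.221, edgeR adjusted p = 0.0398). Neutrophil-like cells rose from 63.5% ± 7.61 to 81.1% ± 4.95 (log2 0.35, SE 0.114, edgeR adjusted p = 0.0283). For dendritic-, T-, NK- and neutrophil-like cells all 3 DIO STN libraries lay on one side of all 3 ND STN libraries, which gives the smallest exact two-sided p of 0.1. Macrophage-like cells gave an exact permutation p of 0.5. B-like cells were 4.39% ± 3.45 in DIO STN and 12% ± 8.15 in ND STN (log2 −1.90, SE 0.841, edgeR adjusted p = 0.0530; exact permutation p = 0.2). Shares depend on each other, since a rise in one class lowers the rest. With neutrophil-like cells left out of the denominator the dendritic-like difference was −1.11 (log2, SE 0.339, edgeR adjusted p = 0.0369), and no other class was called. The macrophage-like difference then turned to 0.38 (log2, SE 0.327, edgeR adjusted p = 0.271).

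Of these 5 calls, the dendritic-like one held without each library in turn (highest adjusted p 0.0323, without DIO STN 3). The T-like call was lost without ND STN 1 (adjusted p = 0.0550), ND STN 2 (0.0571), DIO STN 2 (0.0847) or DIO STN 3 (0.0776). The neutrophil- and NK-like calls were lost without any single library but ND STN 2 (adjusted p from 0.0571 to 0.0847 and from 0.0571 to 0.154). The macrophage-like call was lost without any but ND STN 3 (0.0643 to 0.121), and the B-like class was called without ND STN 2 (adjusted p = 0.0336). The number of classes called was 1 without ND STN 1, DIO STN 2 or DIO STN 3, 2 without DIO STN 1, 3 without ND STN 3 and 4 without ND STN 2. No class was called without a series term (dendritic-like adjusted p = 0.0983) or in RS-0376 alone (dendritic-like log2 −2.24, adjusted p = 0.0915). With a replicate block the macrophage-like call was lost (adjusted p = 0.0607). Within RS-0376 and RS-0384 the log2 ratios were −2.24 and −1.67 for dendritic-like, −1.60 and −2.04 for T-like and −1.11 and −3.52 for NK-like cells. They were −0.81 and −0.087 for macrophage-like, 0.34 and 0.37 for neutrophil-like and −1.10 and −3.81 for B-like cells. Sort gates were not given per library, and DIO STN 3 is the shallowest library.

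Macrophage-like cells of DIO STN had higher levels than those of ND STN for 4 lists that held: fatty acid oxidation, the cell cycle, oxidative phosphorylation and ribosomal proteins. Hypoxia and glycolysis genes were not called (camera adjusted p = 0.161). Of 20 genes of fatty acid oxidation, the burning of fat in mitochondria, 19 had higher fitted values (median log2 0.33, camera adjusted p = 1.01e-07). That list had adjusted p = 0.201 with an estimated correlation, and 5 members passed when adjusted over the list alone against 0 over all genes. Among them, Etfb, which passes electrons from fatty acids to the respiratory chain, was at 221 ± 20 CPM in DIO STN and 131 ± 20.4 in ND STN (SD, n = 3 each; log2 0.77, SE 0.139, edgeR adjusted p = 0.259). Acaa2, the thiolase of this pathway, was at 80.7 ± 24.9 and 49.7 ± 9.37 CPM. Of 25 cell cycle genes 24 had higher fitted values (median log2 0.47, camera adjusted p = 7.44e-09). Here too adjusted p = 0.201 with an estimated correlation, and 5 passed when adjusted over the list alone against 0 over all genes. Stmn1, a regulator of microtubules in dividing cells, was at 104 ± 30.9 and 48.6 ± 17.7 CPM (log2 1.14, SE 0.185, edgeR adjusted p = 0.247). Birc5, an inhibitor of cell death active in mitosis, was at 31.2 ± 8.11 and 16 ± 6.02 CPM.

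Oxidative phosphorylation genes were higher in these macrophage-like cells as well (22 of 25, median log2 0.37, camera adjusted p = 2.61e-09). They had adjusted p = 0.201 with an estimated correlation, and 0 passed when adjusted over the list alone or over all genes. Cox8a was at 1285 ± 84.0 CPM in DIO STN and 899 ± 246 in ND STN (SD, n = 3 each). All 26 ribosomal protein genes had higher fitted values (median log2 0.48, camera adjusted p = 6.42e-24). Again adjusted p = 0.201 with an estimated correlation, and 25 passed when adjusted over the list alone against 0 over all genes. Rpl32 was at 3916 ± 890 and 2611 ± 824 CPM. In RS-0376 alone the adjusted p was 3.18e-09 for fatty acid oxidation, 3.39e-08 for the cell cycle, 0.00126 for oxidative phosphorylation and 2.26e-14 for ribosomal proteins. The monocyte-like cluster held 70.1, 61.2 and 3.87% of macrophage-like cells in DIO STN 1, 2 and 3 and 43.6, 45.3 and 5.85% in ND STN 1, 2 and 3. Whether the lists differ through this mix or within cells was not tested. Markers of T cells in macrophage-like cells summed to 4.87 ± 2.04 CPM in DIO STN and 19.8 ± 6.81 in ND STN, and neutrophil markers to 21695 ± 18659 and 9224 ± 7395.

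Sums of neutrophil-like cells of DIO STN had lower levels of MHC class II genes, which present antigen to helper T cells. Whether neutrophils or free RNA of other cells carry these transcripts stays open. Fitted values were lower for 12 of 14 measured members (median log2 −0.92, camera adjusted p = 2.32e-08). This call had adjusted p = 0.186 with an estimated correlation, and 2 members passed when adjusted over the list alone against 0 over all genes. H2-Aa, the alpha chain of the class II molecule I-A, was at 5.51 ± 3.42 CPM in DIO STN and 26.4 ± 29.6 in ND STN (SD, n = 3 each; log2 −1.82, SE 0.384, edgeR adjusted p = 0.777). H2-Eb1 was at 4.86 ± 3.50 and 20.3 ± 21.8 CPM, and the costimulatory ligand Cd86 at 11.7 ± 4.36 and 23.8 ± 10.8. The T cell effector list was lower as well (12 of 13, median log2 −0.82, camera adjusted p = 3.38e-05). It had adjusted p = 0.186 with an estimated correlation, and 0 passed when adjusted over the list alone or over all genes. The call was lost in RS-0376 alone (adjusted p = 0.0571). Its smallest p belonged to Ccl5, at 0.684 ± 0.404 and 3.99 ± 2.50 CPM. Marker genes of other cells were also at lower levels in neutrophil-like cells of DIO STN. B cell markers summed to 5.54 ± 0.560 CPM against 11.7 ± 5.36 in ND STN, and T cell markers to 4.42 ± 0.895 against 8.84 ± 3.04.

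Fatty acid oxidation genes were higher in neutrophil-like cells of DIO STN (18 of 20, median log2 0.38, camera adjusted p = 2.06e-07). This list had adjusted p = 0.186 with an estimated correlation, and 3 members passed when adjusted over the list alone against 0 over all genes. Cpt1a, which admits fatty acids to mitochondria, was at 38.7 ± 14.8 CPM in DIO STN and 20.4 ± 0.394 in ND STN (SD, n = 3 each), and Acadl at 143 ± 59.8 and 97.6 ± 46.6. Ribosomal protein genes were higher too (26 of 26, median log2 0.29, camera adjusted p = 2.34e-07). For them adjusted p = 0.493 with an estimated correlation, and 0 passed when adjusted over the list alone or over all genes. Rps24 was at 1611 ± 804 and 1112 ± 598 CPM. In RS-0376 alone the adjusted p was 0.000539 for MHC class II, 1.34e-06 for fatty acid oxidation and 0.000215 for ribosomal proteins.

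The only gene called by edgeR was Rims3, a scaffold protein of synapses, in neutrophil-like cells. It was higher in DIO STN, with 3.44 ± 2.20 CPM against 0.190 ± 0.228 in ND STN (SD, n = 3 each; log2 4.18, SE 0.485, edgeR adjusted p = 0.0245). The call was lost without DIO STN 1 (adjusted p = 0.0624), DIO STN 2 (0.168), DIO STN 3 (0.0851) or ND STN 2 (0.274) and in RS-0376 alone (0.240). Without ND STN 3 the count of called genes was 2. In macrophage- and T-like cells edgeR called 0 genes, with 1240 of 13009 and 316 of 8827 at an unadjusted p under 0.05 (483 of 14154 in neutrophil-like cells). Without DIO STN 1 it called 1 gene in T-like cells. Without the filter on low counts it called 331, 12 and 140 in macrophage-, T- and neutrophil-like cells, and other divisions of the 6 libraries gave up to 366, 35 and 318. DESeq2 called 152 genes in macrophage-like cells (144 higher, 8 lower), 0 in T-like cells and 15 in neutrophil-like cells (11 higher, 4 lower). The 15 include H2-Aa, H2-Eb1 and Acot1, an enzyme of fatty acid turnover chosen after its values were seen (61.1 ± 47.5 and 5.83 ± 1.46 CPM; DESeq2 log2 2.75, adjusted p = 0.00177).

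With a replicate block edgeR called 3 genes in T-like cells, named after their values were seen. Lag3, an inhibitory receptor of activated T cells, was at 27.2 ± 13.2 CPM in DIO STN and 95.6 ± 81.6 in ND STN (SD, n = 3 each; log2 −1.89, adjusted p = 0.0458). The T-like sum of DIO STN 3 held 52534 UMIs from 25 cells, so levels of this size rest on few UMIs there. The neutrophil granule genes Mmp8 (log2 3.18, adjusted p = 0.00239) and Wfdc21 (log2 2.61, adjusted p = 0.00239) were higher. Neutrophil markers in T-like cells summed to 7349 ± 4062 CPM in DIO STN and 2691 ± 65.3 in ND STN. By edgeR without the block, T-like cells had the smallest p for Elovl6, which lengthens fatty acids (65.1 ± 12.1 CPM in DIO STN and 26.4 ± 24.1 in ND STN; log2 1.84, SE 0.361, adjusted p = 0.286). Gm10076 (352 ± 84.1 and 149 ± 8.59 CPM) and Tox, a transcription factor of exhausted T cells (73.7 ± 34.9 and 156 ± 33.4; log2 −1.30, SE 0.301, adjusted p = 0.670), followed. A T-like cluster led by Tcf7 and Lef1 held 30.5, 29.8 and 12% of the class in DIO STN 1, 2 and 3 and 21.5, 4.99 and 17.6% in ND STN 1, 2 and 3. One led by Xcl1 and Cd8a held 4.64, 7.69 and 28% and 3.85, 23.9 and 27.1%. Whether Lag3 and Tox differ through the mix of T-like clusters or within cells was not tested.

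In macrophage-like cells Hmgn2, a chromatin protein (85.8 ± 28.6 CPM in DIO STN and 38.9 ± 16.9 in ND STN), and Adgrl3, an adhesion receptor (6.13 ± 1.17 and 1.09 ± 0.757), joined Stmn1 among the smallest p-values (edgeR adjusted p = 0.247 each). In neutrophil-like cells Fgl1, a secreted ligand of LAG-3 (6.54 ± 5.94 and 1.05 ± 0.911 CPM), and Igf2bp3, an RNA-binding protein (4.15 ± 1.86 and 1.63 ± 0.696), followed Rims3. As a limit, other divisions of the 6 libraries gave a smaller p than the real one for oxidative phosphorylation in macrophage-like cells (6.38e-11 against an unadjusted 2.18e-10) and ribosomal proteins in neutrophil-like cells (1.41e-12 against 2.92e-08). For the other lists that held, none of the 9 other divisions did.

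The comparison of ob/ob STN with ob/ob TN asks for the effect of housing temperature in mice whose obesity is genetic. Genes of the type I interferon response were lower in ob/ob STN in each of the 4 classes tested. In neutrophil-like cells 23 of 23 measured members had lower fitted values (median log2 −2.07, camera adjusted p = 2.63e-19). There adjusted p = 0.519 with an estimated correlation, and 20 passed when adjusted over the list alone against 0 over all genes. Irf7, the transcription factor that amplifies interferon production, was at 7.73 ± 1.84 CPM in ob/ob STN and 26.6 ± 10.8 in ob/ob TN (SD, n = 2 each; log2 −1.78, SE 0.480, edgeR adjusted p = 0.666). Ifit2 was at 2.64 ± 0.139 and 17.4 ± 8.16 CPM, and Trim30a, an interferon-induced ubiquitin ligase, at 82.2 ± 27.9 and 211 ± 29.3. In macrophage-like cells all 24 members had lower fitted values (median log2 −1.40, camera adjusted p = 8.69e-11). Here adjusted p = 0.653 with an estimated correlation, and 0 passed when adjusted over the list alone or over all genes. Ifit1 was at 2.43 ± 0.998 and 14.9 ± 6.01 CPM.

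In T-like cells 14 of 17 members of the interferon list had lower fitted values (median log2 −0.90, camera adjusted p = 4.56e-07). They had adjusted p = 0.577 with an estimated correlation, and 5 passed when adjusted over the list alone against 0 over all genes. Zbp1, a sensor of nucleic acids, was at 17.9 ± 1.09 CPM in ob/ob STN and 37.7 ± 5.62 in ob/ob TN (SD, n = 2 each), and Rtp4 at 3.24 ± 2.03 and 17.2 ± 0.548. The median was the same with Rsad2 and Ifit3, at 0 UMIs in T-like cells of 1 group, set at the level that 3 UMIs would give. In epithelial- or tumour-like cells 23 of 24 members had lower fitted values (median log2 −1.49, camera adjusted p = 2.22e-17). In that class adjusted p = 0.454 with an estimated correlation, and 15 passed when adjusted over the list alone against 0 over all genes. Isg15, a ubiquitin-like modifier, was at 2.47 ± 0.801 and 10.5 ± 0.214 CPM (log2 −2.10, SE 0.303, edgeR adjusted p = 0.277). Bst2, which tethers budding viruses, was at 21 ± 1.79 and 40.3 ± 1.90 CPM.

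**Figure D2:**
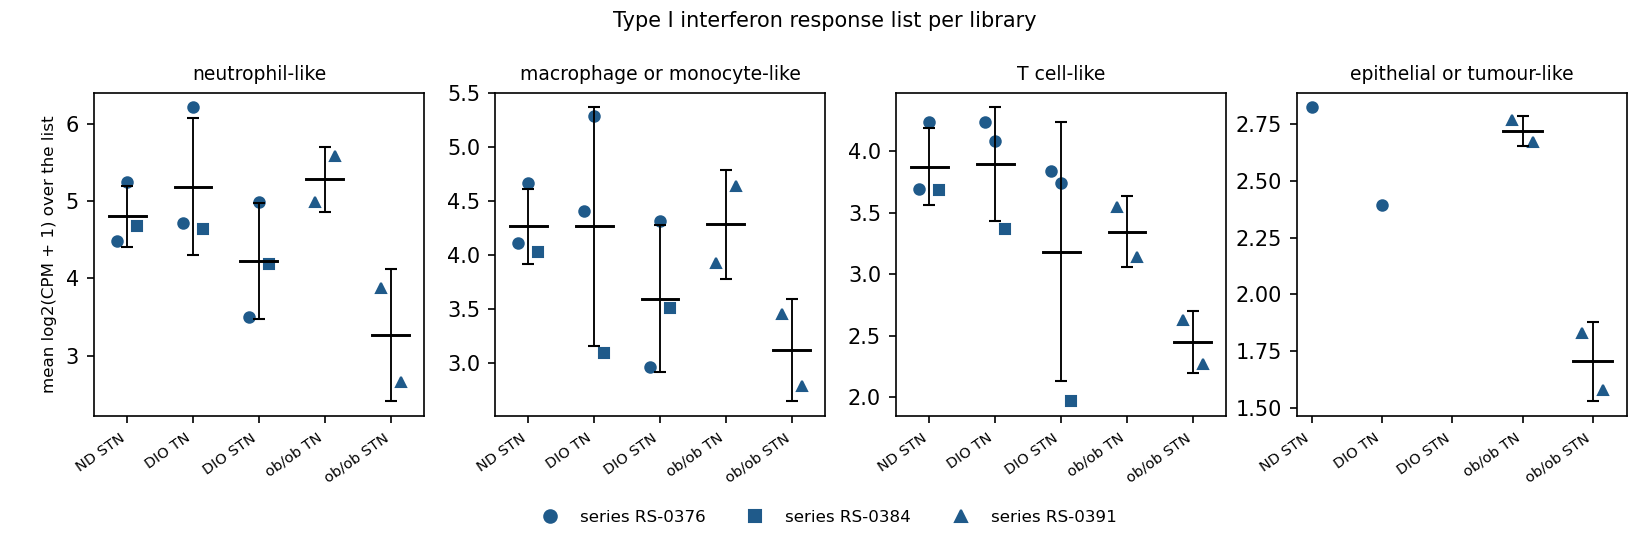
Mean log2(CPM + 1) over the type I interferon list in neutrophil-, macrophage-, T- and epithelial- or tumour-like cells of each library with at least 20 cells of the class, by group; points are libraries, the black line and bars are mean ± SD, and each panel has its own y range, which does not start at 0. Both ob/ob STN libraries lie below both ob/ob TN libraries in all 4 panels (in neutrophil-like cells 3.87 and 2.66 against 4.99 and 5.58).

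Genes of the interferon gamma response were lower in neutrophil-like cells of ob/ob STN (21 of 22, median log2 −0.78, camera adjusted p = 1.38e-06). This call had adjusted p = 0.519 with an estimated correlation. Gbp2, a GTPase that attacks vacuoles of pathogens, was at 4.69 ± 2.40 CPM in ob/ob STN and 24.7 ± 8.03 in ob/ob TN (SD, n = 2 each), and Irgm1 at 5.45 ± 0.868 and 17.4 ± 4.60. The list was also lower in macrophage-like cells (20 of 25, median log2 −0.46, camera adjusted p = 8.02e-05). In them adjusted p = 0.653 with an estimated correlation. Cxcl10, a chemokine that draws activated T cells, was at 7.09 ± 5.76 and 39.8 ± 23.1 CPM there. In neutrophil-like cells all 16 measured genes of MHC class I presentation had lower fitted values (median log2 −0.45, camera adjusted p = 0.00062). Their call had adjusted p = 0.519 with an estimated correlation. B2m, the light chain of class I molecules, was at 370.2 ± 93.6 and 616 ± 7.14 CPM. No gene of these 3 lists and classes passed when adjusted over the list alone or over all genes.

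In epithelial- or tumour-like cells 22 of 23 genes of cholesterol biosynthesis had higher fitted values in ob/ob STN (median log2 0.42, camera adjusted p = 2.88e-09). This pathway had adjusted p = 0.820 with an estimated correlation, and 10 genes passed when adjusted over the list alone against 0 over all genes. Msmo1, an enzyme of this pathway, was at 106 ± 1.21 CPM in ob/ob STN and 71.0 ± 11 in ob/ob TN (SD, n = 2 each). All the ob/ob lists named so far held without each of the 4 libraries. In epithelial- or tumour-like cells the spread in these runs came from the other ob/ob pair alone, a weak check. Epithelial- or tumour-like cells lay in 2 clusters, of which one held 47.9 and 43.1% in ob/ob TN 1 and 2, 37.0% in ob/ob STN 1 and 68.8% in ob/ob STN 2. The class had a median of 4945 UMIs per cell in ob/ob STN 2 against 14082.5 to 17040.0 in the other libraries.

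No gene was called by edgeR in ob/ob STN against ob/ob TN. The counts were 0 in macrophage-, T-, neutrophil- and epithelial- or tumour-like cells, with 753 of 13009, 312 of 8827, 1024 of 14154 and 1244 of 15076 at an unadjusted p under 0.05. DESeq2 called 1, 0, 0 and 7, and edgeR without the filter on low counts 364, 7, 720.0 and 279. Without ob/ob STN 1 edgeR called 1 gene in macrophage-like, 13 in T-like and 630 in epithelial- or tumour-like cells. In the epithelial class that run took its spread from the ob/ob TN pair alone, so its count says little. The DESeq2 gene of macrophage-like cells is Jun, a transcription factor that also responds to tissue dissociation. It was at 709 ± 35.2 CPM in ob/ob STN and 282 ± 68.9 in ob/ob TN (SD, n = 2 each; edgeR log2 1.33, SE 0.237, adjusted p = 0.809; DESeq2 adjusted p = 0.00172). Of 22 dissociation stress genes, 16 had higher fitted values in macrophage-like cells (median log2 0.52, camera adjusted p = 0.000153, but 0.161 without ob/ob STN 1). That list had adjusted p = 0.653 with an estimated correlation, and 4 members passed when adjusted over the list alone against 0 over all genes. Glucocorticoid response genes were higher too (12 of 15, median log2 0.45, camera adjusted p = 0.0176, but 0.222 without ob/ob TN 2), with adjusted p = 0.653 with an estimated correlation. Ifitm10 (10.9 ± 1.18 and 3.23 ± 0.652 CPM) and P2rx7, a receptor for extracellular ATP (119 ± 52.1 and 48.8 ± 8.63), followed by edgeR.

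In T-like cells the smallest p-values belonged to Iigp1, an interferon-induced GTPase (6.48 ± 4.06 CPM in ob/ob STN and 39.9 ± 4.77 in ob/ob TN; log2 −2.61, SE 0.575, edgeR adjusted p = 1), Nars2 (55.3 ± 24 and 14.7 ± 2.96) and Rtp4. In neutrophil-like cells they belonged to Asb4 (1.55 ± 0.401 and 0.177 ± 0.0221 CPM), Gm26535 (12 ± 6.47 and 53.8 ± 5.40) and Gtf2ird1 (11.9 ± 3.55 and 3.49 ± 0.832), all with edgeR adjusted p = 0.666. No immune class differed in share by edgeR (adjusted p = 0.957 for each). With 2 libraries against 2 the smallest exact two-sided p is 0.333. Dendritic-like cells were 0.775% ± 0.180 of immune-named cells in ob/ob STN and 0.759% ± 0.196 in ob/ob TN, and T-like cells 2.38% ± 0.055 and 2.45% ± 1.36. B-like cells were 4.87% ± 3.04 and 3.86% ± 1.73, and NK-like cells 0.315% ± 0.176 and 0.400% ± 0.197. Neutrophil markers summed to 2767 ± 3315 CPM in T-like cells of ob/ob STN and 676 ± 621 in those of ob/ob TN, and to 2903 ± 3025 and 785 ± 314 in epithelial- or tumour-like cells.

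Of the preset genes, Cd274, the ligand of the inhibitory receptor PD-1, was at 158 ± 41.1 CPM in neutrophil-like cells of DIO STN, 307 ± 155 of DIO TN, 253 ± 153 of ND STN (SD, n = 3 each), 254 ± 72.5 of ob/ob STN and 405 ± 16.7 of ob/ob TN (SD, n = 2 each). Against DIO TN its log2 change was −0.95 (SE 0.392, edgeR adjusted p = 1). Pdcd1, which encodes PD-1, was at 219.7 ± 38.1 CPM in T-like cells of DIO STN, 174 ± 5.14 of DIO TN and 156 ± 55.0 of ND STN. Ifng, the interferon of activated T cells, was at 27.8 ± 27.7, 67.9 ± 62.7 and 58.4 ± 8.68 CPM in the same groups. T-like values of DIO STN 3 rest on a sum of only 52534 UMIs. Arg1, which depletes arginine, was at 2337 ± 1162 CPM in macrophage-like cells of DIO STN, 3096 ± 2106 of DIO TN, 3315.5 ± 1622 of ND STN, 3813 ± 254 of ob/ob STN and 4320.0 ± 166 of ob/ob TN. Spp1, a matrix protein of tumour macrophages, was at 2418 ± 1000.3, 3682 ± 2468, 2739 ± 753, 1794 ± 1155 and 4253 ± 252 CPM in that order. Cxcl2 and Il1b, a chemokine and a cytokine of inflamed neutrophils, Vegfa, S100a8, Trem2, Lepr, Cxcl9, Gzmb and Foxp3 were tested and not called. Adrb1, with 68 UMIs in T-like cells, and Lep, with 1, had too few to test.

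The difference between the models was itself tested, as the temperature effect in ob/ob minus that in DIO. In neutrophil-like cells the type I interferon list was lower by more in ob/ob (23 of 23 members, median log2 −1.07, camera adjusted p = 2.01e-06). Its adjusted p = 0.816 with an estimated correlation. The interferon gamma list was lower by more as well (median log2 −0.55, camera adjusted p = 0.00102), with adjusted p = 0.816 with an estimated correlation. In T-like cells all 23 measured cell cycle genes had a lower ob/ob difference (median log2 −1.43, camera adjusted p = 1.40e-06). For that list adjusted p = 0.858 with an estimated correlation. These calls held without each library in turn. A T-like cluster with Mki67 in 98.4% of its cells held 2, 1 and 0 cells in DIO TN 1, 2 and 3. It held 3, 2 and 0 cells in DIO STN 1, 2 and 3, 5 and 5 in ob/ob TN and 3 and 10 in ob/ob STN. With so few cells there, whether the number of cycling T-like cells or levels within cells differ was not tested. No single gene was called by edgeR in macrophage-, T- or neutrophil-like cells (433, 333 and 407 genes at an unadjusted p under 0.05; 138, 4 and 119 called without the filter on low counts), nor by DESeq2 in any of the 3. No class share differed (edgeR adjusted p = 0.950).

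On the mouse assembly GRCm38.p6, Rims3 (ENSMUSG00000032890) lies on chromosome 4 from 120854779 to 120896580. Stmn1 (ENSMUSG00000028832), Jun (ENSMUSG00000052684) and Isg15 (ENSMUSG00000035692) lie on chromosome 4 too, from 134468320 to 134473843, from 95049036 to 95052222 and from 156199424 to 156200818. Rsad2 (ENSMUSG00000020641) lies on chromosome 12 from 26442743 to 26456452, Ifit2 (ENSMUSG00000045932) on chromosome 19 from 34550550 to 34576534 and Cpt1a (ENSMUSG00000024900) on chromosome 19 from 3322326 to 3385735. Gpnmb (ENSMUSG00000029816) and Tmem176a (ENSMUSG00000023367) lie on chromosome 6, from 49036518 to 49058182 and from 48841483 to 48845364. Etfb (ENSMUSG00000004610), Irf7 (ENSMUSG00000025498) and Trim30a (ENSMUSG00000030921) lie on chromosome 7, from 43444072 to 43457800, from 141263183 to 141266499 and from 104409025 to 104465193. H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823. Msmo1 (ENSMUSG00000031604) lies on chromosome 8 from 64718123 to 64733578 and Ccl3 (ENSMUSG00000000982) on chromosome 11 from 83647843 to 83649378. All are annotated as protein-coding genes.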

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

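Chosen only after the result was seen were the tests of single libraries for the interferon list, both tests of the dendritic-like share, all counts over other divisions of the libraries, and the free RNA values per list member with the list tested without some members. The tests of free RNA and of the mix of clusters were set before. Groups of 2 or 3 libraries are too small for a test of single outlying samples.

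The type I interferon list was lower in ob/ob STN than in ob/ob TN in neutrophil-, macrophage-, T- and epithelial- or tumour-like cells, with adjusted p = 0.519, 0.653, 0.577 and 0.454 with an estimated correlation. Without ob/ob STN 1 the list had its highest adjusted p in neutrophil-like cells, 4.67e-13 with the preset correlation. With all libraries and an estimated correlation it was 0.519. The former value does not decide on 1 library as the cause, since ob/ob STN then has 1 library. Other divisions of the DIO libraries also gave very small p-values for this list. The list means were 3.87 and 2.66 in ob/ob STN and 4.99 and 5.58 in ob/ob TN. The direction thus does not rest on 1 library. Against free neutrophil RNA in T-like cells stands that it accounts for at most 4.76% of the list's UMIs there in an ob/ob TN library. A different mix of neutrophil clusters stays open: the median within 4 clusters was −0.32 (log2), inside the range set beforehand for such a cause. That median decides neither way, since the clusters ran from −1.90, with all 24 members lower, to 0.066, and those nearest 0 held as few as 20 and 22 cells in a library, while the interferon-high cluster c3, with 18 and 8 cells in ob/ob STN 1 and 2, had too few to enter it. Housing temperature may lower interferon signalling here, which stays open as the biological explanation.

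The MHC class II and T cell effector lists were lower in neutrophil-like cells of DIO STN than of ND STN, each with adjusted p = 0.186 with an estimated correlation, and the T cell effector call was lost in RS-0376 alone (0.0571). Free RNA of T and NK cells accounts for at most 0.980% of the T cell effector UMIs in neutrophil-like cells, but 92.6% of these come from Ccl3, Ccl4 and Zeb2. It would account for at least 50% of 4 of the 13 tested members, the only ones with an unadjusted p under 0.05, and without these 4 the list had camera adjusted p = 0.0862 (adjusted p = 0.476 with an estimated correlation), so it stays open. Free RNA of B cells, dendritic cells and macrophages would account for 112% of the MHC class II UMIs or more in each of the 6 libraries, above the 50% set beforehand for it as the cause, but with 678% in ND STN 1 the estimate is too high, for a reason that was not tested, and the source stays open. By this estimate it would account for at least 50% of 12 of the 14 tested members. Of the 5 members with an unadjusted p under 0.05, 4 are among these. The other 2 tested members are too few to test as a list. Diet-induced obesity, which may change antigen presentation by neutrophils, was not tested apart from these.

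The dendritic-like share was lower in DIO STN than in ND STN. More neutrophils lower the other shares alike, but with neutrophils left out of the denominator the log2 difference was still −1.11 (SE 0.339), which argues against this as the whole cause. Each group has 2 libraries of RS-0376 and 1 of RS-0384, so the design balances the series, and comparing them is no test of it. The log2 ratio was −2.24 in RS-0376 and −1.67 in RS-0384, the latter from 1 library against 1. The share was not called in RS-0376 alone or without a series term. Losses of fragile cells during tissue dissociation and the sort gates were not tested. Diet-induced obesity may lower dendritic cell numbers, as the biological explanation left open.

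The temperature effect in ob/ob minus that in DIO was tested itself, and the lists below passed camera with the preset correlation. In macrophage-like cells they were lower for interferon gamma (median log2 −0.29, adjusted p = 0.0175), type I interferon (−0.44, 0.0220), hypoxia and glycolysis (−0.14, 0.0409), the unfolded protein response (−0.26, 0.0175) and the cell cycle (−0.54, 0.00549). They were higher for the glucocorticoid response (0.50, 0.00624) and dissociation stress (0.68, 0.00123). All of these had adjusted p = 0.896 with an estimated correlation. Each call was lost without 1 library: DIO TN 3 for interferon gamma (0.413) and type I interferon (0.981), DIO TN 1 for hypoxia (0.904), ob/ob STN 2 for the unfolded protein response (0.449), ob/ob TN 1 for the cell cycle (0.917), DIO STN 2 for glucocorticoid (0.0883) and ob/ob STN 1 for dissociation stress (0.125), these being the highest values.

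In T-like cells the difference was lower for cholesterol biosynthesis (median log2 −0.61, camera adjusted p = 0.0451) and the cell cycle (−1.43, 1.40e-06) and higher for the glucocorticoid response (0.69, 0.0366). All had adjusted p = 0.858 with an estimated correlation. Cholesterol biosynthesis was lost without DIO TN 1 (0.208) and glucocorticoid without DIO STN 2 (0.161), as the highest values, while the cell cycle stayed at 0.00256 or less. In neutrophil-like cells the difference was lower for interferon gamma (median log2 −0.55, adjusted p = 0.00102), type I interferon (−1.07, 2.01e-06), MHC class I (−0.34, 0.0116) and mitochondrially encoded genes (−0.46, 0.00350). It was higher for glucocorticoid (0.69, 0.00149) and dissociation stress (0.30, 0.0102). These had adjusted p = 0.816 with an estimated correlation. It was higher also for the cell cycle (1.22, 0.0170) and ribosomal proteins (0.21, 0.0466), which had adjusted p = 0.983 with an estimated correlation. Calls held for type I interferon (at most 0.0226), interferon gamma (0.0412) and glucocorticoid (0.0423). They were lost for MHC class I (0.317) and mitochondrially encoded genes (0.383) without DIO TN 3, for the cell cycle (0.763) and ribosomal proteins (0.695) without ob/ob STN 2, and for dissociation stress (0.415) without ob/ob STN 1. The ob/ob libraries being a series of their own, model and series cannot be told apart.

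The 9 antibody tags of the 6 RS-0376 libraries enter no comparison and carried counts in each class. The mean of the library medians was highest in T-like cells for CD127 (22.75 UMIs per cell, with 20 in neutrophil-like cells) and CD69 (16.7 and 13), in NK-like cells for NK1_1 (22.8 and 15.8), and in neutrophil-like cells for CCR4 (17.8). It was highest in macrophage-like cells for CD44 (765.3 and 699), F4_80 (30.5 and 24.5), CD62L (20.8 and 20.7), CD25 (14.3 and 13.2) and KLRG1 (10.2 and 9.17). The files hold no control for unbound antibody, and the highest value of each of the 9 tags lay within 1.5 times of its neutrophil level. CD44 was lower in T- (212), dendritic- (164), NK- (131) and B-like cells (78.2).

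For groups of 3 libraries, 10 divisions of the 6 libraries exist, too few for a share under 0.05. In DIO STN against ND STN camera called 13 lists in macrophage-like cells (highest other division 11), 5 in T-like cells (9) and 9 in neutrophil-like cells (11), and 1, 4 and 4 of the 10 divisions gave as many. In DIO STN against DIO TN it called 3 (11), 2 (8) and 8 (12), and 10, 6 and 8 divisions gave as many. The counts of 11 and 8 lists are several times the real ones and point to a structure of the samples that the groups do not explain. EdgeR called 0, 0 and 1 genes against ND STN (highest other 1, 0 and 1, with 10, 10 and 2 divisions as many) and 0, 0 and 0 against DIO TN (highest other 0, 1 and 0, with 10 as many in each). Of the class shares it called 5 against ND STN (highest other 0, with 1 division as many) and 0 against DIO TN (highest other 2, from DIO STN 1 and 2 with DIO TN 1, with 10 as many). Some list counts moved by over 1.5 times without 1 library. Against ND STN the 13 fell to 5 without DIO STN 1, and the 5 went to 3 (DIO STN 1 or DIO STN 2), 1 (ND STN 2) or 11 (DIO STN 3). Against DIO TN the 3 went to 5 (DIO TN 1 or DIO STN 2), 7 (DIO TN 3) or 6 (DIO STN 3), the 2 to 0 (DIO TN 1, DIO STN 1 or DIO STN 2) or 5 (DIO TN 3), and the 8 to 13 (DIO TN 1 or DIO TN 3). The classes called against ND STN were 1 without ND STN 1, DIO STN 2 or DIO STN 3, 2 without DIO STN 1 and 3 without ND STN 3.

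Pairs by replicate number are not in the labels, and 1 pair of DIO STN with DIO TN correlated at only 0.0962 in T-like cells. Replicate 2 pairs lay within the range of differently numbered libraries of RS-0376, so the pairing is uncertain. The real division parts all 3 such pairs, as do 3 of the 9 others, while 6 part 1 pair. In DIO STN against ND STN the others that part 3 pairs gave 7 to 10 lists in macrophage-like cells, 1 to 9 in T-like cells and 4 to 10 in neutrophil-like cells, and those that part 1 gave 8 to 11, 0 to 6 and 5 to 11. In DIO STN against DIO TN the ranges were 3 to 9, 0 to 2 and 6 to 12 for 3 pairs, and 4 to 11, 1 to 8 and 3 to 10 for 1 pair. With a replicate block the T-like genes called against ND STN were 3.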

How the results depend on the processing

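Chosen only after the data were seen were the fit on RS-0376 alone, leaving out libraries for the gene lists, the crossed pairing, counting unnamed sub-clusters as dendritic, shares with neutrophils left out of the denominator, and the counts for other divisions of the libraries without a filter on low counts. Apart from leaving out libraries, 1358 of the log2 changes of named genes kept direction and side of the threshold, 97 came to pass it, 4 no longer did and 17 changed sign. Of the class shares 136 values kept direction and side, 13 no longer passed, 1 came to pass and 6 changed sign. Of the lists 88 kept their call and 44 lost it. Of 154 genes named, per class and comparison, 26 had another sign in 54 of 2286 values.

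Without the filter on low counts edgeR called 113, 331 and 364 genes in macrophage-like cells (DIO STN against DIO TN, DIO STN against ND STN, ob/ob STN against ob/ob TN), 5, 12 and 7 in T-like cells, 151, 140 and 720 in neutrophil-like cells, 279 in epithelial- or tumour-like cells, and 138, 4 and 119 for the difference between the models in macrophage-, T- and neutrophil-like cells. Of these, 327 of 331 (macrophage-like, against ND STN) and 708 of 720 (neutrophil-like, ob/ob) pass the filter, so the calls come mostly from genes that were tested with it too. Their median unadjusted p with the filter was 0.0219 and 0.0483, with 0.674 and 0.367 as the highest. Without the filter, other divisions of the same libraries gave 79 to 606 genes in macrophage-like, 2 to 28 in T-like and 21 to 710.0 in neutrophil-like cells against DIO TN, and 46 to 366, 6 to 35 and 57 to 318 against ND STN. As many genes as the real division came from 7, 8 and 5 of the 10 divisions against DIO TN and from 2, 7 and 4 against ND STN, the real one included. The count of 331 in macrophage-like cells was reached by 1 other division. The counts of 606, 28 and 710.0 are several times the real ones and point to a structure of the samples that the groups do not explain. In macrophage-like cells, divisions that kept DIO STN 1 with DIO TN 1 gave 344 to 606 genes, and the rest, the real one included, 79 to 180. The same divisions gave 21 to 710 against 26 to 200 in neutrophil-like cells and 8 to 24 against 2 to 28 in T-like cells. Shared deviations of replicate 1 thus go with the macrophage-like counts only. For ob/ob and for the difference between the models no other divisions were run, and how the filter acts on the estimated spread was not tested.

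DESeq2 called 152 genes in macrophage-like cells against ND STN and 1 in ob/ob, 2 in T-like cells against DIO TN, 15 in neutrophil-like cells against ND STN and 7 in epithelial- or tumour-like cells. With only the groups compared, edgeR called 1 gene in T-like cells against DIO TN, 7 against ND STN and 0 in neutrophil-like cells against ND STN. Without a series term it called 0 there, as it did with cells named one by one and in RS-0376 alone. RS-0376 alone gave 1 gene in T-like cells against DIO TN and 14 against ND STN. The former is Retnlg, as with only the groups compared. The 14 include Retnlg, Lcn2, S100a8, S100a9 and Wfdc21, beside Tox and Satb1. The 7 with only the groups compared include Lcn2, Mmp8 and Wfdc21, beside Elovl6 and Spp1. Apart from those set beside them, these are genes abundant in neutrophils, whose markers were higher in T-like cells of DIO STN, as given above. No class share was called against ND STN without a series term (0) or in RS-0376 alone (0). Counting unnamed sub-clusters as dendritic left the dendritic-like share called (log2 −1.84, SE 0.406, edgeR adjusted p = 0.0106). The cause was not tested for any of these.

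With the correlation estimated from the data, camera called 0 lists in each of the 13 results. In simulated data of the same size that setting called 0 of 9 lists changed 1.5-fold, but genes were drawn there independently of each other. Such data hold no correlation between genes. They do not show how correlation acts, and each simulated test was 1 draw. For the type I interferon list in ob/ob, simulated camera adjusted p was 0.0503 in macrophage-like, 0.0564 in T-like and 0.389 in neutrophil-like cells. The real list had medians beyond 1.5-fold and a higher adjusted p in each of these classes (0.577 in T-like cells). This argues against low power of the simulated kind as the whole cause for this list in ob/ob. For the other lists it stays open. Without a series term camera called 7 lists in macrophage-like cells against ND STN, 1 in T-like cells against DIO TN and 5 in neutrophil-like cells for the difference between the models. In RS-0376 alone it called 5 in macrophage-like cells and 7 in T-like cells against DIO TN, and 10 in T-like and 5 in neutrophil-like cells against ND STN.

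The replicate block called 3 genes in T-like cells against ND STN, and it changed no other call among the lists that held and, but for the macrophage-like share, among the class shares. The ob/ob libraries share only a number: their pairs correlated at 0.0248 in macrophage-like, 0.0198 in T-like, 0.253 in neutrophil-like and −0.116 in epithelial- or tumour-like cells, and the block called 2 genes in T-like cells there. Those 2 genes are Camp and Wfdc21, neutrophil granule genes. The crossed pairing called 34 genes in epithelial- or tumour-like cells.

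A called value, the macrophage-like share against ND STN, changed sign with neutrophils left out of the denominator (log2 0.38, SE 0.327). The other shares and genes that changed sign were called by no test. Without a series term the log2 change of the dendritic-like share against DIO TN was −0.14 and that of Foxp3 in T-like cells −0.010. With cells named one by one the dendritic-like share changed to −0.021 against DIO TN and −0.18 in ob/ob, Gzmb in T-like cells against ND STN to 0.053, and Foxp3, Gzmb and Pdcd1 in ob/ob to −0.10, −0.076 and −0.19. With the stricter cell filter the ob/ob dendritic-like share was −0.035. The T-like share in ob/ob was 0.069 with the replicate block and 0.072 by limma. RS-0376 alone gave −1.67 for Cxcl9 in macrophage-like cells and 0.023 for Vegfa in neutrophil-like cells against DIO TN, and 0.30 for Cxcl2, 0.029 for Il1b and 0.26 for Gzmb against ND STN. Vegfa was 0.0019 with no filter and 0.026 with the block. Gzmb against ND STN was 0.00016 with only the groups compared and 0.017 with the block, and against DIO TN −0.0077 with doublets kept. Pdcd1 in ob/ob was −0.046 with doublets kept and −0.0050 with only the groups compared. The cause was not tested.

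Leaving out 1 library in turn gave 0 to 1 genes in macrophage-like cells in ob/ob, 0 to 1 in T-like cells against ND STN (1 without DIO STN 1), 0 to 13 in T-like cells in ob/ob, 0 to 2 in neutrophil-like cells against ND STN (2 without ND STN 3) and 0 to 630 in epithelial- or tumour-like cells, the highest in ob/ob always without ob/ob STN 1. Runs in the epithelial class took their spread from the other ob/ob pair alone. Classes called against ND STN were 1 to 4. Lists called in macrophage-like cells were 2 to 7, 5 to 15 and 7 to 13 in the order of comparisons above, and 2 to 12 for the difference between the models. In T-like cells they were 0 to 5, 1 to 11, 5 to 15 and 1 to 10, in neutrophil-like cells 6 to 13, 6 to 13, 6 to 10 and 4 to 10, and in epithelial- or tumour-like cells 7 to 13. Adjusted p for the difference between the models ran from 7.67e-05 to 0.904 for hypoxia and 1.66e-14 to 0.917 for the cell cycle in macrophage-like cells, and from 4.47e-09 to 0.763 for the cell cycle in neutrophil-like cells, each with a change of direction.

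Log2 changes that reached both signs when 1 library was left out are those of shares and genes that no test called. Against DIO TN these were dendritic-like (−0.27 to 0.41) and T-like shares (−0.41 to 0.43), and in ob/ob B-like (−0.50 to 0.88), dendritic-like (−0.23 to 0.32), NK-like (−1.06 to 0.28) and T-like shares (−0.52 to 0.67). In macrophage-like cells against DIO TN they were Arg1 (−0.72 to 0.11), Cxcl9 (−1.78 to 3.86), Lepr (−1.74 to 0.63), Spp1 (−1.07 to 0.29) and Trem2 (−0.44 to 0.096), against ND STN Lepr (−0.64 to 0.063), Spp1 (−0.39 to 0.045) and Trem2 (−0.36 to 0.19), and in ob/ob Cxcl9 (−2.23 to 2.24) and Trem2 (−0.31 to 0.36). In neutrophil-like cells against DIO TN they were Il1b (−0.29 to 0.18), S100a8 (−0.30 to 0.39) and Vegfa (−0.46 to 0.20), against ND STN Cxcl2 (−0.33 to 0.33) and Il1b (−0.24 to 0.028), and in ob/ob Cxcl2 (−0.65 to 0.18), Il1b (−1.13 to 0.071), S100a8 (−0.079 to 1.13) and Vegfa (−0.0099 to 0.84). In T-like cells they were Gzmb against DIO TN (−0.29 to 0.30) and ND STN (−0.63 to 0.36), and in ob/ob Foxp3 (−0.15 to 0.52), Gzmb (−0.19 to 0.84) and Pdcd1 (−0.37 to 0.51).

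Simulated 2-fold changes were called in 5.10, 11.2 and 13% of genes in T-like cells and in 18.75, 15.6 and 5% in neutrophil-like cells, in the order of comparisons above.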

Other observations

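The within-cluster values, the cluster sizes and the whole-library levels given here were looked at only after the lists had been tested, and none of them is a test. Within single clusters of the ob/ob libraries the type I interferon list was lower in ob/ob STN in macrophage-like cluster c14 (median log2 −1.0, 23 of 24 members lower) and c16 (−0.91, 24 of 24), in epithelial- or tumour-like cluster c22 (−1.02, 23 of 24) and c17 (−0.43, 19 of 24), and in dendritic-like cluster c23 (−1.72, 21 of 24). T-like cluster c19-3 had −0.46 (17 lower) and B-like cluster c27 −0.067 (14 lower). Of the unnamed clusters, c24-8 had −0.79 (21 lower) and c18 0 (10 lower, 8 higher). Of the neutrophil-like clusters, c7 had −1.90 (24 lower), c6 −0.46 (22 lower), c2 −0.17 (13 lower) and c8 0.066 (9 lower). A cluster of 3375 neutrophil-like cells, c3, led by Rsad2, Ifit1 and Cxcl10, took 39.8% of its cells from DIO TN 2. It held 69 and 139 cells in ob/ob TN 1 and 2 and 18 and 8 in ob/ob STN 1 and 2, under the 20 needed for a within-cluster value.

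Lepr, the leptin receptor gene, summed over all kept cells to 16.1 to 28.8 CPM in the ob/ob libraries and 0.745 to 6.36 CPM in the others. Of its 6183 UMIs in macrophage-, T- and neutrophil-like cells, 6027 were in macrophage-like cells. These made up 19.6 and 23.6% of all cells in ob/ob TN and ob/ob STN and 9.93 to 15.9% in the other groups, as means. The part of this mix was not tested, and model and series cannot be told apart. Lep had 1 UMI, in ob/ob STN 2, and 3' tags do not read the ob mutation. In macrophage-like cells the nerve growth and axon guidance list was lower in DIO STN than in ND STN (13 of 13 members, median log2 −0.12, camera adjusted p = 0.0280, but 0.259 without DIO STN 1; adjusted p = 0.633 with an estimated correlation). It was lower in ob/ob STN than in ob/ob TN too (11 of 13, median log2 −0.19, camera adjusted p = 0.0339, but 0.584 without ob/ob STN 2; adjusted p = 0.653 with an estimated correlation). Adrenergic signalling genes were higher in ob/ob STN in T-like cells (13 of 17, camera adjusted p = 0.0411, but 0.592 without ob/ob TN 2; adjusted p = 0.646 with an estimated correlation). They were higher in epithelial- or tumour-like cells as well (12 of 18, camera adjusted p = 0.0446, but 0.372 without ob/ob TN 2; adjusted p = 0.827 with an estimated correlation).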
